A study of Mus musculus with 6 samples.

How the data were processed

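The samples were neocortex RNA of 6 null mutant mouse embryos of embryonic day 14, each hybridised to an array of 2 colours together with 1 pool of RNA from 6 wild-type animals. Per the labels, the mutant was in cy3 on 3 arrays and in cy5 on the other 3. The labels call the mutants biological replicates. The pool counts as 1 control sample.

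The deposited values, read here as log2 ratios, were made by the authors, and the steps that made them, the scanner, the background correction and the normalization, are not given in the sources used here. The deposited table states neither the log base nor the direction. A base of 10 is excluded, because the largest size of 7.84 would exceed the range of a scanner, and base 2 was assumed; a natural logarithm is not excluded, and with it every value would need to be multiplied by a constant. The means of the arrays lay within 0.01 of 0, so the arrays appear centred on their mean. The medians were 0.05, 0.04, -0.23, -0.13, 0.04 and -0.005 on replicates 1 to 6. Scanner intensities were not used here, so that probes near background could not be told from bright ones, and slide and scan batches are unknown. The alternative of removing dim probes could therefore not be run.

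Probes were named through the platform annotation, with 6269 probes carrying 1 gene symbol, 6 several and 581 none. Of these, 6250 probes matched the reference by gene identifier and 0 symbols needed an update. The table held 776 probes without any value and 3763 with a value on all 6 arrays. No name was taken from a probe with several symbols.

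The direction was set by a rule fixed before the data were examined, as were the gene lists, the rule for named genes and the main fit. The rule looked first at the targeted gene, which is not reported here, then at sex-linked genes beyond 2 in size, and last at correlations between orientations. Only Xist passed that limit, on replicates 5 and 6, and its reading assumes a pool of both sexes in similar shares. The Y-linked genes gave no clear answer. The last step favoured the other reading, clearly so by Spearman's rho, and was not followed, so the main reading of replicates 1 to 3 departs from that step. It rests on Xist and was chosen after its values were seen. Under the other reading replicates 1 to 3 were turned, so that the sign of replicates 5 and 6 stayed fixed.

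Each probe with at least 2 values in each dye orientation was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the mutant effect as intercept and the dye orientation as a term. The test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 4958 probes, of which 4574 had a gene name. Gene lists were tested with camera at a preset correlation of 0.01, on ratios averaged per gene. Camera needs complete values, so this test ran on 3359 genes with values on all 6 arrays. Lists with fewer than 5 such members were not tested, which left 24 of 28 lists, since the lists kept as checks were left out too. Counts of members above and below 0, and medians over members, come from the limma estimates of 4417 genes. Adjusted p of lists are adjusted over the 24 lists.

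Named genes are, where none passes, the 10 with the smallest unadjusted p in each direction, up to 4 members of each list with the smallest p with 1 probe per gene, and at most 2 unnamed probes in each direction. Values of named genes are those of that probe. Hk1, Igf1r, Tnc and Hspa8, among others, have 2 probes, so their values are those of 1 of them. Where another gene is named, it was chosen after its values were seen.

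Both tests were first run on simulated data with the real pattern of missing values and the real width of each array. In the simulation of mutants against the pool over 4958 probes, 200 probes were changed. Of those changed by 1 on the log2 scale 58% were recovered, and of those changed by 2, 96%, with 1 false call. Without replicates 3 and 4, over 4728 probes, these shares were 84.5% and 98.9%, with 7 false calls. The simulated arrays shared noise only between replicates 3 and 4, held no dye effect, and had changes of equal size on every array. The real arrays also correlated within other pairs, at 0.364 for replicates 1 and 2 and 0.211 for 5 and 6. The recovered shares are therefore not the power of the real fit, and 0 passing probes do not exclude changes of these sizes. The simulated list test over 3359 genes called the 1 shifted list and 0 of the unchanged ones. Its genes were simulated independently of each other, so it does not cover lists whose genes move together.

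Alternatives were the other reading of the sign, no dye term, median centring, centring with scaling to a common median absolute deviation, complete probes, robust moderation (statmod 1.5.0), array weights, leaving out each replicate, averaging per gene, a threshold of 0.1, no moderation, an estimated correlation and fry. Alternatives added after the data were seen were leaving out replicates 3 and 4, turning them, a random block for pairs of similar arrays, each orientation alone, and camera on the statistics of all tested genes. Correlations, resampling and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.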

Results

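Neocortex RNA of 6 null mutant mouse embryos, described in the labels as synaptically silent, was compared with wild-type RNA at embryonic day 14 on 6 arrays of 2 colours. Each array held 1 mutant embryo against the same pool of RNA from 6 wild-type animals. The mutant carried cy3 on replicates 1, 2 and 3 and cy5 on replicates 4, 5 and 6. The question behind the design is which genes of the embryonic cortex depend on synaptic activity. The pool is the only control sample, so the test sets the ratio against 0 and leaves out the spread between wild-type animals. The number of arrays limits the precision.

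The value table held a log ratio for 6856 probes. Values are read here as log2 of mutant over pool, with base 2 assumed, so that a positive value stands for more RNA in the mutant. The arrays had between 4396 and 5678 values each. They differed in width, with a standard deviation of 0.35 on replicate 2 and 1.09 on replicate 3.

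The direction of the ratio was not settled for all arrays, and the signs below are those of one reading. Xist, the RNA of the inactive X chromosome found in female cells, lay at -3.17 on replicate 5 and -2.58 on replicate 6. If the pool held both sexes in similar shares, which is not known, a mutant can fall that far below it but cannot exceed it by as much. That places the mutant in the numerator on these arrays. A pool with few females would allow a larger excess. On replicates 1, 2, 3 and 4 Xist lay at 0.61, 0.71, 0.31 and 0.24, under the limit of 2 set beforehand. The Y-linked genes gave no clear answer. On replicates 1 and 2, Kdm5d lay at -0.36 and -0.78, Eif2s3y at 0.28 and 0.15 and Zfy1 at 0.09 and -0.22. The largest values were on replicates 3 and 4, with Eif2s3y at -1.34 and -0.64 and Zfy1 at 1.52 and 1.79. Kdm5d lay at 0.34 and 0.09 there, and Uty at 0.72 and 0.02. On replicates 5 and 6, Kdm5d lay at 0.18 and 0.16, Eif2s3y at 0.17 and -0.42, Zfy1 at -0.62 and -0.88 and Uty at -0.13 and 0.26. The last step of the rule, the mean correlation over probes, favoured turning replicates 1 to 3. Between orientations the mean was -0.039 for Pearson's r and -0.127 for Spearman's rho, against -0.025 and 0.038 within them, and without the pair of replicates 3 and 4 it was -0.118 and -0.223. Replicates 1 to 3 were nevertheless taken as deposited, a choice made after the Xist values were seen. Turned, they would put the mutants of replicates 1 and 2 at a moderate deficit of Xist, which a female or a male embryo should not show against a mixed pool. Of the 20 genes named next, 12 change sign under the other reading.

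No gene differed between the mutants and the wild-type pool past the threshold. Of 4958 probes tested, 0 had an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.372. At an unadjusted p under 0.05 there were 88 probes, 53 with positive and 35 with negative estimates, where chance gives 247.9. Under the other reading of the sign, 0 probes passed and 228 lay under an unadjusted p of 0.05. Weighting the arrays by how well they follow the fit gave 2 passing probes and 600 under an unadjusted p of 0.05. The weights were 0.10 and 0.31 on replicates 3 and 4, against 1.40 to 4.01 on the others, so this comes close to leaving them out. Leaving out replicates 3 and 4, an alternative chosen after seeing the data, gave 1 passing probe and 642 of 4728 under an unadjusted p of 0.05. Leaving out replicate 3, 5 or 6 alone gave 0 passing probes and 154, 58 or 49 under an unadjusted p of 0.05.

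Gng3, a G protein gamma subunit of neurons, had the largest estimate among the 10 genes with the smallest unadjusted p and a positive sign. Its ratio was 2.01 ± 0.40 (SE, n = 6; adjusted p = 0.921), positive on 6 of 6 arrays. The values were 3.87, 4.50 and 1.30 with the mutant in cy3 and 0.58, 1.53 and 0.29 with the mutant in cy5. With array weights, limma gave Gng3 2.48 ± 0.20 (SE, n = 6; adjusted p = 0.0089), which passed, while without replicates 3 and 4 it stood at 2.55 ± 0.24 (SE, n = 4; adjusted p = 0.1257) and did not pass. The signalling scaffold Mapk8ip1 stood at 0.43 ± 0.11 (SE, n = 6), the RNA-binding protein gene Elavl1 at 0.56 ± 0.15 (SE, n = 6), Ppig at 0.42 ± 0.12 (SE, n = 6) and the zinc finger gene Zfp868 at 0.33 ± 0.11 (SE, n = 6). Each of these 4 was positive on all 6 arrays. Dlg3, a postsynaptic scaffold gene, was positive on 5 of 6 arrays at 0.87 ± 0.23 (SE, n = 6), or 0.53 without replicates 3 and 4. Spry1, an inhibitor of growth factor signalling, had 0.78 ± 0.15 (SE, n = 5), from 1.42, 1.68 and 1.91 in cy3 to 0.07 and -0.30 in cy5. Plcb4, Clip2 and Ppp2r5d, with 0.49, 0.46 and 0.96, completed these 10, and Ppp2r5d fell to 0.59 without replicate 2. The adjusted p was 0.921 for each of them.

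Among the 10 genes with a negative sign, Car5a, a mitochondrial carbonic anhydrase, had a ratio of -0.67 ± 0.16 (SE, n = 6) and was negative on 6 of 6 arrays. It is the only gene of these 10 with a value on every array. All the others lack a value on replicate 3, the array with the largest standard deviation, so their small p leaves that array out. Abcb11 at -1.20, Ifnar2 at -0.77, the potassium channel gene Kcnq5 at -0.63 and the imprinted gene Zim1 at -0.57 were negative on all 4 arrays with a value, namely replicates 1, 2, 5 and 6. Camk2d, a calcium and calmodulin dependent kinase, had -0.98 ± 0.17 (SE, n = 5), with -1.62 and -2.27 in cy3 and -0.22, -0.23 and 0.38 in cy5. The calmodulin gene Calm3 stood at -0.51 and the adenylyl cyclase gene Adcy8 at -0.74. Tmem9b and Cradd stood at -0.64 and -0.84. None of the 10 passed, each with an adjusted p of 0.921.

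Probe 6385, which carries no gene name here, had the smallest p of all probes tested. Its ratio was -1.47 ± 0.18 (SE, n = 6; adjusted p = 0.372), with values from -1.83 to -0.64 on the 6 arrays. It passed with array weights at -1.66 ± 0.10 (SE, n = 6; adjusted p = 0.0017) and without replicates 3 and 4 at -1.71 ± 0.07 (SE, n = 4; adjusted p = 0.0292). Another unnamed probe, 6395, stood at -0.97. Of the unnamed probes on the higher side, 6386 had 0.89 and 4132 had 0.31.

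**Figure D1:**
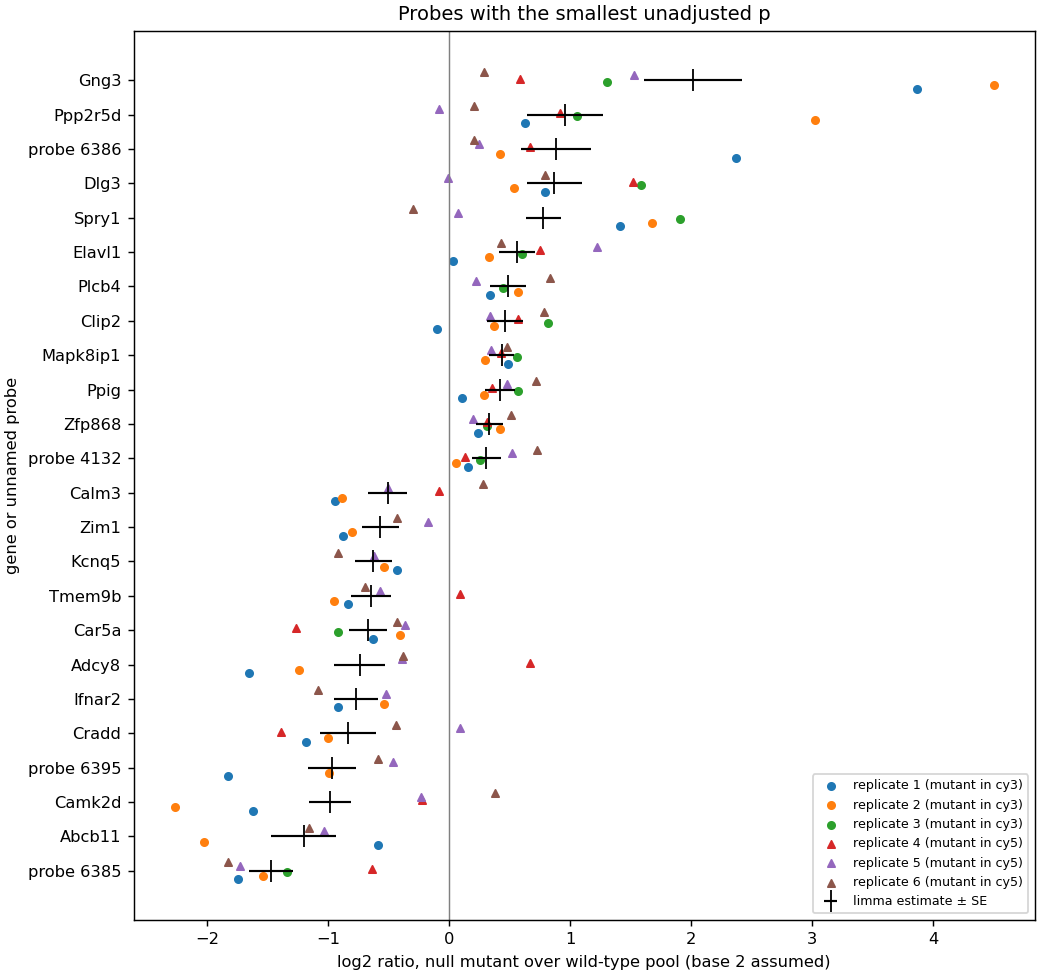
Log2 ratio of mutant over pool (horizontal axis, base 2 assumed) for the 20 genes and 4 unnamed probes with the smallest unadjusted p in each direction. Circles and triangles are single arrays with the mutant in cy3 and cy5, and black bars are the limma estimate and its SE; Gng3 spreads from 0.29 to 4.50, while the values of probe 6385 stay between -1.83 and -0.64.

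Genes of neuropeptide secretion were followed because the mutants are synaptically silent. Of 26 neuropeptide precursors with a probe, 5 had enough values, all 5 had negative estimates with replicates 3 and 4 included, and 0 passed over all genes or adjusted over the list alone. Their estimates ran from -0.17 to -0.07, with somatostatin, Sst, at -0.17 ± 0.15 (SE, n = 5) and the natriuretic peptide gene Nppc at -0.17 ± 0.20 (SE, n = 6). The shared sign rests on replicates 3 and 4: without them Nppc stood at 0.13, Nppb at 0.06 and Iapp at 0.11, and Sst at -0.13. This list had too few members with complete values for the main set test. Camera on the statistics of all 5 gave the direction down with an adjusted p of 0.4327. Among 13 dense core vesicle genes, 6 lay above 0 and 7 below, with chromogranin A, Chga, at 0.26 ± 0.11 (SE, n = 6) and carboxypeptidase E, Cpe, at 0.13 ± 0.12 (SE, n = 6), or 0.23 without replicates 3 and 4 and 0.07 without replicate 5. Camera gave this list an adjusted p of 0.944. The 27 activity-regulated genes had 7 above and 20 below 0 with a median of -0.10, among them Rgs2 at -0.23 and Ier3 at -0.24, and an adjusted p of 0.994. Without replicates 3 and 4 Ier3 stood at -0.13, and the mean of the list's array medians turned from -0.05 to 0.02. In these lists 0 members passed, also adjusted over the list alone.

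Synaptic genes gave no passing member or list. Of 26 genes of synaptic vesicles and their release, 11 lay above and 15 below 0, with dynamin 1, Dnm1, at 0.22, or 0.13 without replicate 6, and Rab3a at -0.21, or -0.01 without replicates 3 and 4 (camera adjusted p = 0.748). Of 23 postsynaptic receptor and scaffold genes, 11 lay above and 12 below, with Dlg3 as above, gephyrin, Gphn, at 0.27 ± 0.12 (SE, n = 6) and Homer2 at -1.10 ± 0.44 (SE, n = 5). Homer2 lay at -3.35 on replicate 1 and at -0.59, 0.63, -1.13 and -0.20 on replicates 2, 4, 5 and 6, so its estimate rests largely on replicate 1, without which too few cy3 values were left for a fit. Camera gave this list an adjusted p of 0.282. The 19 ion channel and transporter genes had 10 above 0, including the calcium channel subunit gene Cacna2d1 at 0.56, and an adjusted p of 0.524. Among 34 axon guidance and adhesion genes 23 lay above 0, including Ntn1 at 0.45, with an adjusted p of 0.304. The neurotrophin and growth factor list had 14 of 23 above 0, with Igf1r at 0.39, and an adjusted p of 0.508. Cacna2d1 stood at 0.36 and Igf1r at 0.26 without replicates 3 and 4. Under the other reading of the sign the postsynaptic and axon guidance lists passed as higher, with adjusted p of 0.0204 and 0.0101.

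Cell identity lists did not separate mutant and pool either. Of 28 progenitor genes 15 lay above 0, with Eomes, a factor of intermediate progenitors, at 0.33 ± 0.12 (SE, n = 6) and Tnc at -0.45 ± 0.18 (SE, n = 6), or -0.17 without replicates 3 and 4, and the camera adjusted p was 0.414. Of 32 proliferation genes 16 lay above and 16 below 0, with Top2a at 0.22, or 0.13 without replicate 4, and Pcna at 0.29, or -0.0013 without replicates 3 and 4 (adjusted p = 0.546). Postmitotic projection neuron genes had 31 of 42 below 0 and a median of -0.09, with Elavl3 at -0.42 and Stmn3 at -0.26 but Pou3f3 at 0.22 (adjusted p = 0.282). On replicate 3 alone the median of this list was -0.81, and without replicates 3 and 4 Elavl3 stood at -0.12. Under the other reading it passed as higher, with an adjusted p of 0.0305. Interneuron genes had 11 of 18 below 0, with Dlx2 at -0.37 and Gad2 at -0.25, or -0.10 without replicate 1 (adjusted p = 0.748). Cell death and p53 genes had 11 of 19 above 0, with Bid at -0.27 and Bad at 0.25, or -0.09 and 0.10 without replicates 3 and 4 (adjusted p = 0.961). In each of these lists 0 members passed, also adjusted over the list alone.

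Markers of neighbouring regions and other cell types gave a measure of how alike the dissected tissue was. The ganglionic eminence and striatum list had 4 of 10 above 0, with Six3 at 0.49 (camera adjusted p = 0.414). Genes of other brain regions had 9 of 15 above 0, with Tcf7l2 at 0.78, or 0.42 without replicate 6 (adjusted p = 0.272). The choroid plexus and hem list had 9 of 12 above 0, with Msx1 at 0.66, or 0.38 without replicate 4 (adjusted p = 0.524). Meninges and vessel genes had 14 of 27 above 0, with the collagen gene Col5a2 at 0.70 and decorin, Dcn, at -1.28 (adjusted p = 0.282). Without replicate 1 the meninges and vessel list passed as higher, with an adjusted p of 0.0123. In camera the direction was lower without replicate 3 (19 genes, adjusted p = 0.4672) and without replicates 3 and 4 (23 genes, adjusted p = 0.3175). Those tests held more genes than the 14 with values on all 6 arrays. The change of direction can therefore not be credited to the arrays alone. Over these 14 genes the median was 0.34, 0.12, 0.17 and 0.18 on replicates 3 to 6. It was -0.13 and -0.07 on replicates 1 and 2. Erythroid genes had 4 of 11 above 0, with Car2 at -0.13, or -0.03 without replicates 3 and 4 (adjusted p = 0.664). Glial genes had 5 of 7 below 0, with Slc1a3 at -1.02 ± 0.89 (SE, n = 6), Mbp at -0.77 ± 0.70 (SE, n = 5) and Olig2 at -0.24, but Gja1 at 0.24 (adjusted p = 0.71). Without replicate 1, Slc1a3 stood at -0.09 and Mbp at -0.15. For both genes these are values of 1 of 2 probes. Averaged per gene, the lowest member of the glial list lay at -0.55. Mbp stood at -1.39 and Olig2 at 0.05 without replicates 3 and 4, and Gja1 at 0.11 without replicate 3 and 0.14 without replicate 5. Microglia and macrophage genes had 1 of 7 above 0, C1qb at 1.30 ± 0.75 (SE, n = 6), and too few complete members for the main set test. Camera on the statistics of all 7 gave the direction down (adjusted p = 0.3399), as did camera without replicates 3 and 4 (7 genes; adjusted p = 0.3175). C1qb stood at 5.06 and 2.41 on replicates 3 and 4 and its estimate without them was 0.09. No member of these lists passed, also adjusted over the list alone.

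Ribosomal protein genes formed the 1 list of 24 that passed the set test, with negative ratios. Of 31 genes 28 lay below 0 and the median ratio was -0.22, with Rps7 at -0.37, Rpl3 at -0.31 and Rpl6 at -0.31, or -0.16, -0.03 and -0.0063 without replicates 3 and 4. Rpsa, the member with the smallest unadjusted p, stood at -0.84, and at -0.90 without replicates 3 and 4. It lay at -2.37 on replicate 1, without which it stood at -0.62. These are values of 1 of its 2 probes. Averaged per gene, the lowest member of the list lay at -0.44. Camera with its preset correlation gave an adjusted p of 6.31e-05. The adjusted p was 0.733 with an estimated correlation, since the genes moved together with a correlation of 0.778. The medians of the list were 0.26 and 0.17 on replicates 1 and 2, -0.88 and -0.48 on replicates 3 and 4, and -0.004 and -0.39 on replicates 5 and 6. An exact two-sided sign-flip test of these 6 medians gave p = 0.281, where 0.0312 is the smallest p that 6 arrays allow. Without replicates 3 and 4 the median was 0.02, on the other side of 0, and without replicate 3 alone it was -0.04, each without a pass. No single member passed, also adjusted over the list alone.

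Other lists of metabolism and stress did not pass. Oxidative phosphorylation genes had 13 of 18 below 0 with a median of -0.14, among them the succinate dehydrogenase gene Sdhb at -0.33, or -0.05 without replicates 3 and 4, and a camera adjusted p of 0.282. This list passed as lower under the other reading of the sign (adjusted p = 0.0053), with scaled arrays (adjusted p = 0.0424) and with array weights (adjusted p = 0.0484). Heat shock genes had 12 of 15 below 0, with Hspe1 at -0.36 (adjusted p = 0.282), and medians of -0.77 and -0.66 on replicates 3 and 4 against 0.22 and 0.09 on replicates 1 and 2. Hypoxia and glycolysis genes had 15 of 23 below 0, with Hk1 at -0.27, or -0.10 without replicates 3 and 4 (adjusted p = 0.71). The Hk1 values are those of 1 of its 2 probes. Averaged per gene, the lowest member of this list lay at -0.22. Genes of the secretory pathway and its stress response had 13 of 24 above 0, with Xbp1 at 0.29, or 0.06 without replicates 3 and 4 (adjusted p = 0.442). Cholesterol synthesis genes had 7 of 10 above 0, with Cyp51 at 0.38, or 0.25 without replicate 3, and Dhcr7 at 0.28, or 0.17 without replicate 6 (adjusted p = 0.282). In these lists 0 members passed, also adjusted over the list alone.

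**Figure D2:**
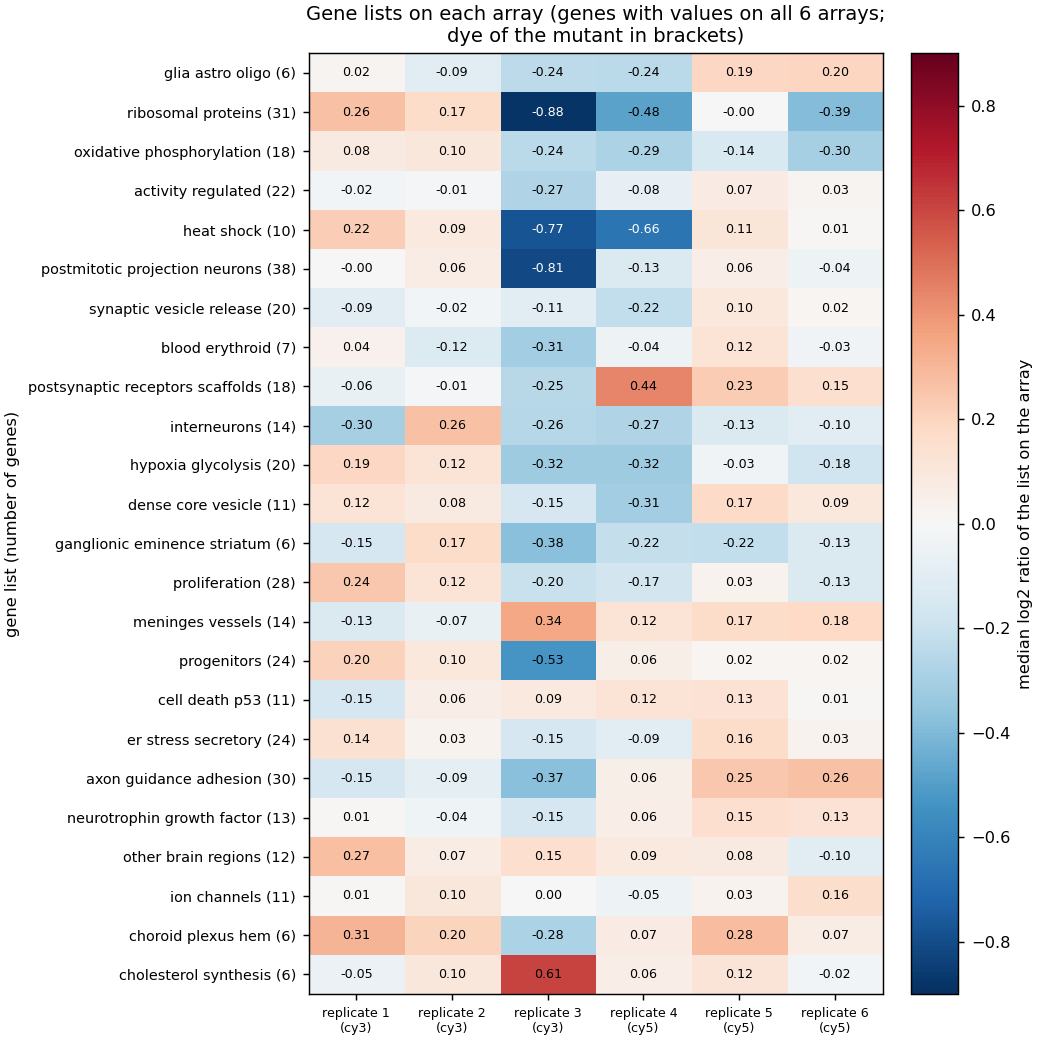
Median log2 ratio of mutant over pool for each of 24 gene lists (vertical axis, number of genes in brackets) on each of the 6 arrays (horizontal axis), over genes with a value on every array, with colour from blue for negative to red for positive. The ribosomal protein list runs from -0.88 on replicate 3 to 0.26 on replicate 1.

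The dye orientation also left 0 probes past the threshold in limma, with 228 at an unadjusted p under 0.05. This count was 105, 126, 610, 104 and 74 without replicate 1, 2, 3, 5 and 6 in turn, and 1107 without replicates 3 and 4. Over all probes shared by a pair of arrays, Pearson's r averaged -0.025 within an orientation and -0.039 between orientations, and Spearman's rho averaged 0.038 and -0.127. The difference between these means was not tested. Replicates 1 and 2 correlated at 0.364 and replicates 5 and 6 at 0.211. The highest correlation, 0.590, joined replicates 3 and 4, which carry the mutant in opposite dyes. Replicate 3 correlated at -0.365 with replicate 5. These correlations run across probes, which are not independent replicates.

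**Figure D3:**
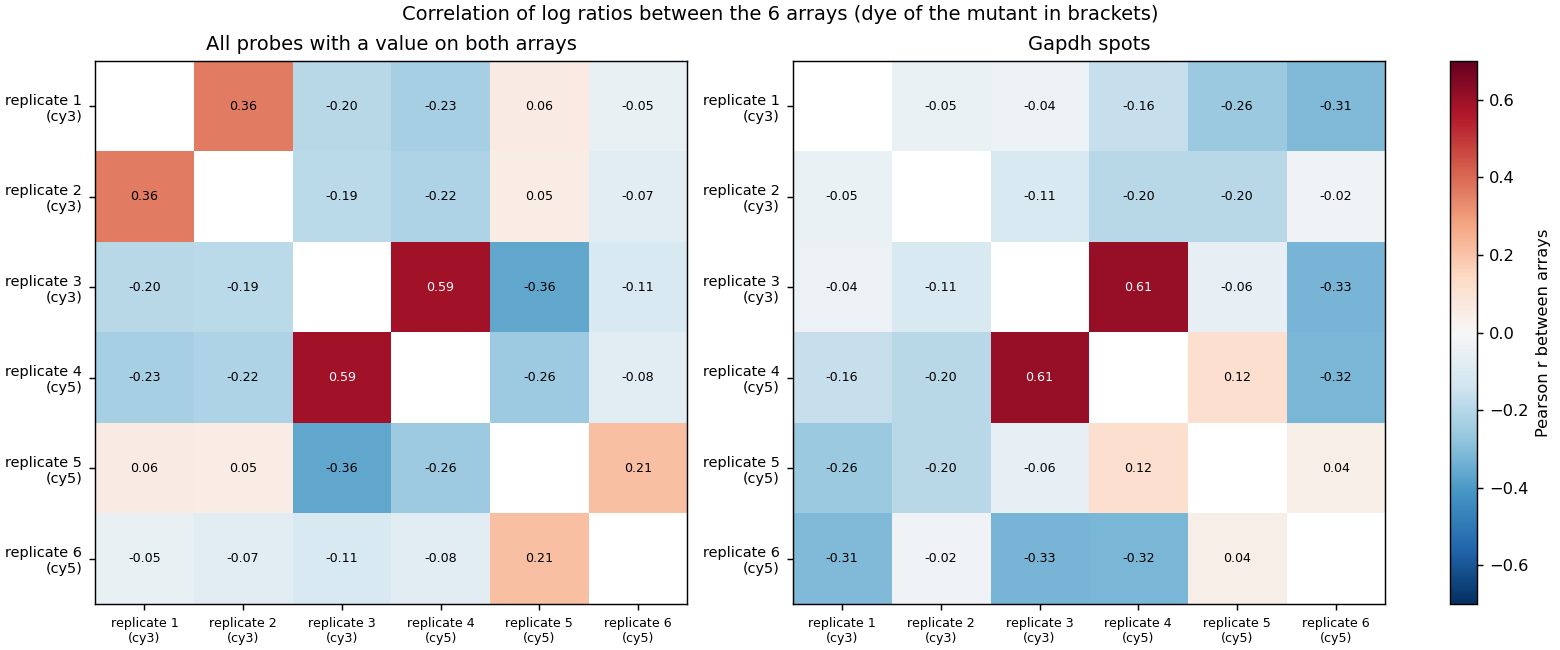
Pearson's r of the log ratios between each pair of the 6 arrays (both axes), over all probes with a value on both arrays on the left and over 78 Gapdh spots on the right. Replicates 3 and 4 stand out in both panels, with 0.590 and 0.611.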

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

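Of the tests in this part, that of dim probes was written down before its result was seen, median centring of the ribosomal protein list was chosen before the data were examined, and all others came after.

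Among 135 sets of values of named probes and array summaries, 9 had 1 array far from the rest, where chance gives about 1 in 20. Replicate 4 was the far array for Dcn at 1.14, with the others from -2.08 to -1.50, for Gphn at 0.64, with the others from 0.13 to 0.26, and for Cpe at -0.31, with the others from 0.11 to 0.31. Replicate 3 was the far array for Cntfr at 3.95, against -0.23 to 0.71, and for Olig2 at -1.53, against -0.20 to 0.36. Replicate 1 was far for Bdnf at -1.05, against -0.15 to 0.09, and for the unnamed probe 6386 at 2.37, against 0.21 to 0.67. Replicate 2 was far for Ppp2r5d at 3.03, against -0.09 to 1.06. The standard deviation of replicate 3, at 1.09, stood apart from 0.35 to 0.62 on the others.

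Replicates 3 and 4 correlated at 0.590 across opposite dyes and stood apart from the other arrays. The 78 Gapdh spots share 1 gene, yet between these arrays Pearson's r was 0.611 (95% bootstrap interval 0.401 to 0.771) and Spearman's rho 0.524. Over the other pairs r ran from -0.328 for replicates 3 and 6 to 0.120 for 4 and 5. Spearman's rho ran from -0.427 for replicates 1 and 6 to 0.337 for 4 and 6. A technical effect on spots may be part of the correlation, but Gapdh spots also correlated, negatively, in some other pairs. Probes lacking a value on another array lay 0.276 above fully measured ones on replicate 4 (95% bootstrap interval 0.203 to 0.359) and 1.38 on replicate 3, against at most 0.202 in size on the rest. That was -0.202 on replicate 1 (95% bootstrap interval -0.226 to -0.178), whose median absolute deviation was 0.31 against 0.49 on replicate 4. In size, replicate 4 therefore does not clearly stand apart from replicate 1. A trend with probe brightness may be part of it, more clearly on replicate 3. Turning the sign of both arrays leaves their correlation unchanged, so it is no source of it, but a wrong sign stays open for their values opposite to the other arrays: of 8 probes at least 0.5 in size with 1 sign on replicates 1, 2, 5 and 6, 87.5% had the opposite sign on both, or 6 of 8 counting only values of at least 0.1 in size there, while probe 6385 kept its sign. No biological explanation was tested, since the design holds 1 group.

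The ribosomal protein list lay below 0 with a median of -0.22. Different medians of whole arrays do not account for its place below 0, since with each array centred on its median the list stayed at -0.178. It also passed then, but this cannot decide the question for the call. Camera compares the list with the other genes, which centring shifts alike. Without replicates 3 and 4 its median was 0.0244, so the call may rest on the values of its genes on these arrays. A lower level in every mutant was not shown, with an exact sign-flip p of 0.281 over 6 array medians that lie on both sides of 0, and stays open.

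At an unadjusted p under 0.05 there were 88 probes where chance gives 247.9. Of the 32 sign patterns of the 6 arrays, 20 gave as many or more and 13 as few or fewer, and the highest other gave 687. Chance is therefore not excluded in either direction, and the arrays hold a structure that the real pattern does not follow. Whether it is apart from genotype is open. A wrong sign of replicates 3 and 4 is not excluded, and the pattern with both turned gave 663. With replicates 3 and 4 kept but turned, the share was 13.4% of probes, so their width alone need not lower the count. Without them it was 13.6%, so their values opposite to the other arrays may lower it. In these 4 arrays the real pattern gave 642 probes and the pattern that sets replicates 1 and 2 against 5 and 6 gave 1107, while no other of the 8 patterns exceeded 300. The pattern with 1107 is also the dye contrast of these 4 arrays and the other reading of the sign. For that count, a dye effect, a wrong sign of replicates 1 and 2 and similarity within pairs cannot be told apart. The excess without replicates 3 and 4 may come from similarity within pairs of arrays, but this was not separated from the other 2. Over all 6 arrays, a random block for such pairs gave 4 probes in place of 88, and no block was fitted to the 4 arrays alone.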

How the results depend on the processing

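Alternatives named as added in the processing part were chosen after the data were seen. The count of 0 passing probes in limma was also found under every alternative but 3: array weights gave 2, leaving out replicates 3 and 4 gave 1, and turning replicates 3 and 4 gave 3, namely Scel at -1.65, Tuba4a at -1.84 and Dcn at -1.66. The 88 of 4958 probes at an unadjusted p under 0.05 became 228 under the other reading, 185 with scaled arrays and 600 with array weights. A random block gave 4, and turning replicates 3 and 4 gave 663. The other counts are over other numbers of probes. Complete probes gave 51 of 3763, or 1.36% against 1.77% in the main fit. Leaving out replicates 3 and 4 gave 642 of 4728, and 1107 of 4728 under the other reading. The cy5 mutants alone gave 277 of 5676, where chance gives 283.8. Leaving out 1 replicate gave 49 to 154. The passing lists, 1 in the main test, numbered 4 under the other reading, 2 with scaled arrays, 2 with array weights, and 0 with an estimated correlation, with fry, or without replicates 3 and 4 with either correlation; leaving out 1 replicate gave 0 to 2. The median of the ribosomal protein list, -0.2175, was kept with an estimated correlation and fry, which ended the call, was -0.0628 under the other reading, also without a call, was -0.1777 with median centring and -0.0861 with scaled arrays, each with the call kept, and reversed to 0.0244 without replicates 3 and 4 with either correlation. Leaving out 1 replicate moved it between -0.3118 and -0.0399, and only without replicate 3 did the call end. The cause was not tested beyond the tests of replicates 3 and 4. The dye effect left 0 probes under median centring and each left-out replicate, but 31 with array weights. Under the other reading it is by construction the mutant effect of the main test. Of 130 named probes, none of which passed, 74 changed sign under the other reading, 70 with replicates 3 and 4 turned, 17 of 122 without replicates 3 and 4, and 0 with median centring. Robust moderation and complete probes do not apply to camera, which was complete already. Removing dim probes was not run.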

Other observations

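The probes below and the tests of this part were chosen after the data were seen. Of 8 probes with a size of at least 0.5 and 1 sign on replicates 1, 2, 5 and 6, 7 lay on the other side of 0 on both replicates 3 and 4, among them Prrc2a with only -0.0005 on replicate 4, so that 6 did so by at least 0.1. Scel lay between -2.29 and -1.60 on the 4 arrays and at 1.00 and 1.24 on replicates 3 and 4. The tubulin gene Tuba4a lay between -2.59 and -1.56 on the 4 arrays and at 1.87 and 1.25 on the others. Cebpd and Cyp21a1, with means of -0.79 and -0.82 over the 4 arrays, stood at 2.47 and 2.48 on replicate 3. The chaperone gene Hspa8 averaged -0.62 over the 4 arrays, and Prrc2a 0.67. Probe 6385 alone of the 8 had the same sign on all 6 arrays.

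Over the 3763 probes with complete values, 54 had the same sign on all 6 arrays, or 1.44%, where independent arrays without any effect give 3.12%. Of the 32 sign patterns 19 gave as many or more, and the highest other gave 526.

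Slc1a3 and Mbp, genes of glia, ranged from -4.97 to 1.67 and from -3.02 to 1.97 over the arrays, each on 1 of 2 probes. C1qb, a gene of microglia, ranged from -0.57 to 5.06. No explanation was tested for these ranges.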
